A study of Mus musculus with 18 samples.

How the data were processed

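The deposited table holds 26143 genes in 18 columns, 1 per library, and its values are log2 units: per the submitters' processing notes, reads were demultiplexed with bcl2fastq 1.8.4, trimmed with Trimmomatic and counted with featureCounts on the build mm10, and the deposited log2 values follow from those counts. Libraries were made with the TruSeq Stranded mRNA LT kit. The aligner, the annotation and the method behind the scaled totals are not given in the sources used here. The name of the deposited file speaks of counts. The values themselves equal log2 of reads plus 1 minus log2 of a scaled library total, since 100% of the values returned whole reads to within 0.001 when the smallest value of a column was taken as 0 reads. The scaled totals were 0.939 to 1.12 times the sum of reads.

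The plan fixed before the data were examined assumed a count table and count models. The deposited unit is log2 and count models were kept to deposited counts, so limma 3.58.1 in R 4.3.3 was used on the deposited log2 values, with the mean-variance trend and Benjamini-Hochberg adjustment over the genes tested in each comparison. 1 fit with a mean per group held all 18 libraries, with 14 residual degrees of freedom, and gave the 6 comparisons between the 4 groups. Genes were tested when at least 3 libraries held 0.635 CPM or more, which is 10 reads at the median depth, and the sum over libraries was 15 reads or more, which left 15235 genes. An adjusted p under 0.05 was called. In this text "higher" and "lower", "rose" and "fell" refer to the first group of a comparison. Libraries held from about 14592000 to about 18176000 reads, and inside a set of 3 the variance between libraries was 1.34 to 3.59 times that of counting error. Alternatives were other scaling factors, other filters, voom with sample quality weights, the 2 compared groups alone, a replicate block, a muscle marker covariate, a 2-fold minimum, and each library, and after the data had been seen each set, left out in turn. After the data had been seen, TMM factors, log2 of CPM plus 1 and 6 set means were added. An interaction of the 2 alleles was not tested, since the group without either allele is another tissue.

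49 gene lists were fixed before the data were examined, in 3 kinds, which are 28 pathways, 4 technical lists and 17 cell types. The 37 with at least 5 tested genes were tested with camera of limma at a preset correlation of 0.01. Each test was repeated with the correlation estimated from the data, and with fry, which asks only whether a list's genes move one way. Of the 66 calls by camera over the 6 comparisons, 10 held with the estimated correlation.

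Genes are named by a rule fixed before the data were examined. It takes Trp53, Pik3ca, Cdkn1a and Mdm2, then up to 8 higher and 8 lower genes per comparison by log2 change, then up to 4 genes of each list by adjusted p. Genes of the second kind had an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the groups, and predicted, RIKEN, pseudogene and antigen receptor genes were left out. Some genes that the rule names are not reported here. Each gene named as changed lay without overlap between its 2 groups, apart from Fdps in E20/p53 against E20. A fold for a gene with 0 reads in a group is given as a lower bound, over the group, against a floor of 3 reads. Floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. No fold is given where a group held 1 to 3 reads. Positions come from GENCODE M21, which uses the same build.

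Reads were simulated from the real means and library sizes, without set shifts, with 200 genes changed. Each comparison recovered 100% of 100 genes changed 2-fold and 100 changed 4-fold. Recovery with set shifts was not tested. For E20/p53 against E20, 7 of 14441 unchanged genes were called. In a simulation of E20/p53 against E20 with no group change, in which each set of 3 libraries was shifted on its own with an SD of 1 log2 unit per gene, 5944 of 15299 genes were called with 18 libraries and 0 with the 6 set means.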

Results

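RNA was measured by sequencing in 18 mouse libraries in 4 groups, which the labels describe as squamous epithelium. The WT group holds 3 libraries of wild type esophagus. The other groups are tongue: 3 libraries with 1 mutant p53 allele, R172H (p53), 6 with the PIK3CA allele H1047R (E20), and 6 with both alleles (E20/p53, the double mutants). R172H is a p53 change in the DNA-binding domain, and H1047R is a change that activates the catalytic subunit of PI3-kinase. LSL in the labels means that a stop element flanked by loxP sites keeps an allele silent until Cre recombinase removes it. The labels do not give sex, and they do not say which libraries came from a tumour. Libraries held from about 14592000 to about 18176000 counted reads over 26143 genes. The table gives log2 of reads plus 1 over a scaled library total, and levels below are CPM on that scale, as mean ± SD. Nothing states that the libraries of a group come from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

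The libraries fell into 6 sets of 3. Replicates 1 to 3 and 4 to 6 of E20 formed separate sets, as did those of E20/p53, and WT and p53 formed 1 set each. Pearson's r across genes was 0.991 to 0.994 for the 18 library pairs inside a set. It was 0.859 to 0.944 for the 18 pairs that join both sets of a group, and 0.809 to 0.948 for the 117 pairs from different groups. Genes are not independent replicates, so these values describe likeness only. The variance between libraries was 1.34 to 3.59 times that of counting error inside a set and 19.6 to 64.7 times it between the sets of a group. The sets were seen in the data and are not groups of the study, so no test was made between them. With the libraries averaged to 6 set means, limma called between 0 and 8 genes in each of the 6 comparisons, an alternative chosen after the libraries had been examined. Genes without overlap between groups made up 22.5% to 82.2% of those tested. Chance shares over sets, below, are ceilings, as they take sets never to overlap.

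**Figure D1:**
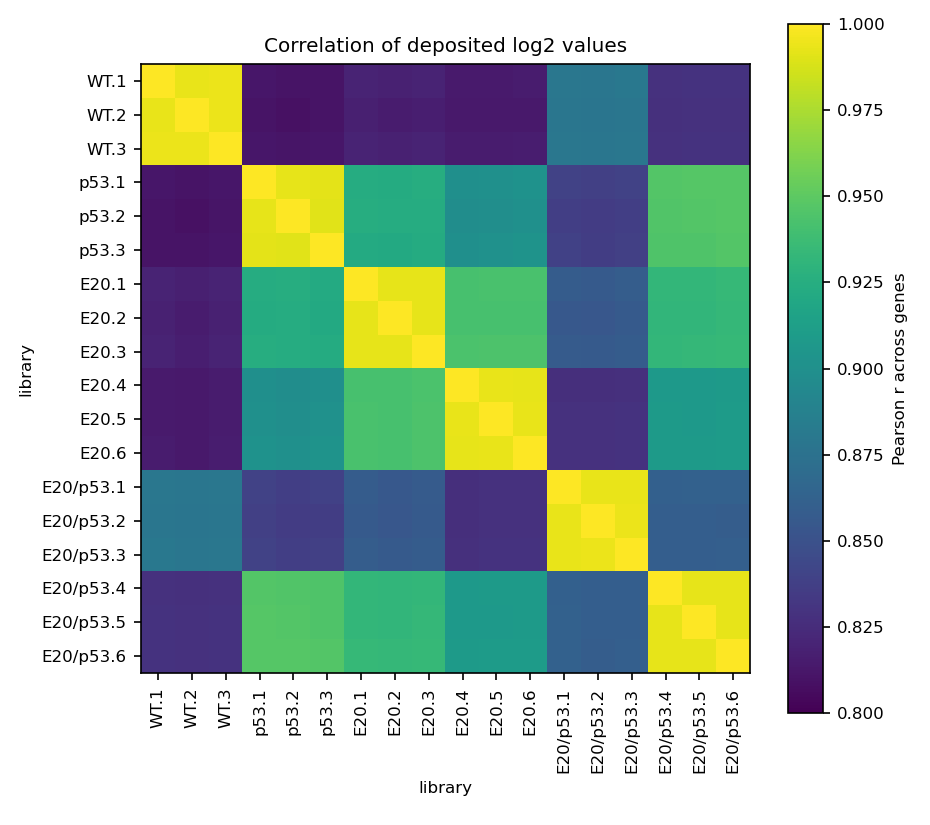
Pearson correlation (colour) across genes of the deposited log2 values for each pair of the 18 libraries, which stand on both axes by group and replicate. Pairs inside a set of 3 reach 0.991 to 0.994, and pairs between the 2 sets of E20/p53 or of E20 lie between 0.859 and 0.944.

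Marker genes, chosen for display after their values were seen, differed between the sets (n = 3 libraries in each). Krt5 and Krt14 encode the keratin pair of basal keratinocytes. In E20/p53 libraries 1 to 3 they stood at 127 ± 8.78 and 483 ± 10.6 CPM, and in E20 libraries 1 to 3 at 6.51 ± 1.35 and 66.5 ± 7.29 CPM. In WT Krt5 was at 0.0784 ± 0.068 CPM. Krt14 was at 13.4 ± 0.769 CPM in WT, 0.695 ± 0.142 in p53, 0.0222 ± 0.0385 in E20 4 to 6 and 0.199 ± 0.0586 in E20/p53 4 to 6. Krt18, a keratin of simple epithelia, was at 228 ± 8.18 CPM in WT. Col1a1 and Col1a2 encode the chains of type I collagen, which fibroblasts secrete. Col1a2 stood at 3323 ± 154 CPM in p53, 6365 ± 346 and 8634 ± 521 in the E20 sets and 7391 ± 372 in E20/p53 4 to 6. In E20/p53 1 to 3 Col1a2 was at 1.58 ± 0.0573 CPM, and in WT at 1344 ± 65.4. Pecam1 of endothelial cells did not exceed 3.25 ± 0.12 CPM in any set, and Ptprc of leukocytes did not exceed 0.0874 ± 0.0403. Xist, the RNA of the inactive X chromosome, was at 893 ± 90.4 and 1304 ± 41.7 CPM in the E20 sets and at most 0.826 ± 0.0581 elsewhere. The Y-linked gene Eif2s3y had 0 reads in WT and E20, and was at 95.3 ± 4.78 CPM in p53 and 103 ± 5.36 and 67.6 ± 2.07 in the E20/p53 sets. WT thus held neither marker, with Xist at 0.677 ± 0.0516 CPM, so its sex stays open in each comparison with WT.

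**Figure D2:**
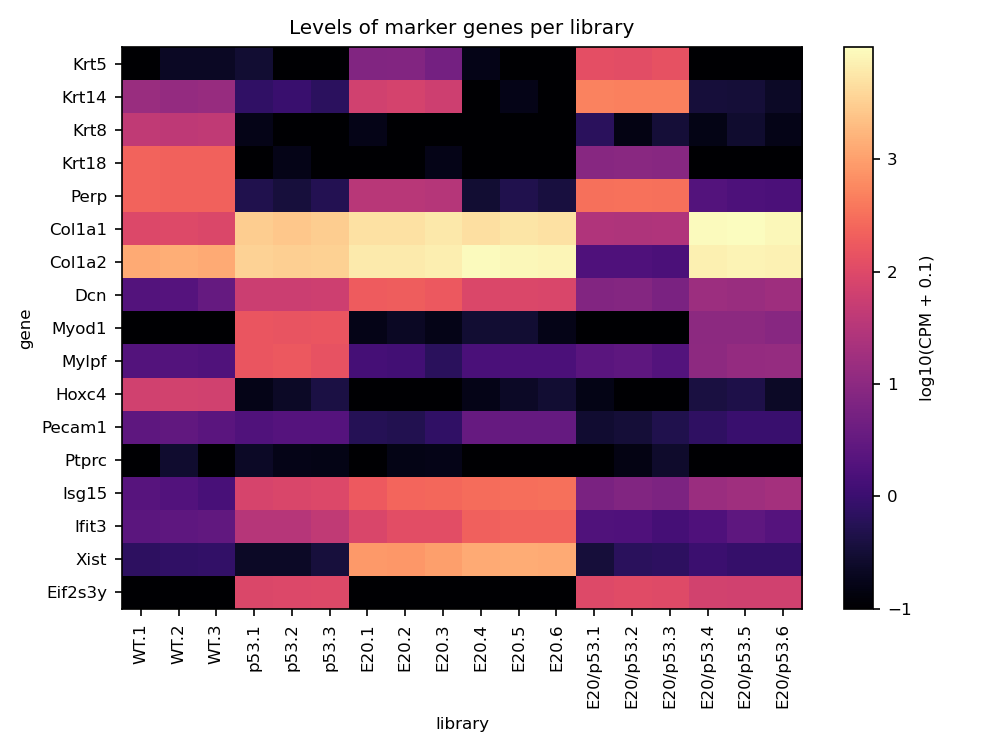
Level of 17 marker genes (vertical axis) in each of the 18 libraries (horizontal axis), as the colour of log10 of CPM plus 0.1. Krt5 and Krt14 are brightest in E20/p53 libraries 1 to 3, with means of 127 and 483 CPM, and Xist is bright in the 6 E20 libraries.

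Trp53 and Pik3ca are the genes whose alleles define the groups, and Cdkn1a and Mdm2 are targets that wild type p53 activates. Cdkn1a encodes the cell cycle inhibitor p21, and Mdm2 encodes the ligase that degrades p53. In mm10, GENCODE places Trp53 on chromosome 11 at 69580359 to 69591873, and Pik3ca on chromosome 3 at 32397671 to 32468486. Cdkn1a lies on chromosome 17 at 29090976 to 29100727, and Mdm2 on chromosome 10 at 117688875 to 117710758. Trp53 was lowest in WT, at 25.8 ± 0.895 CPM (n = 3). It was higher than in WT in p53 libraries (log2 1.66, SE 0.21, adjusted p = 8.6e-06), in E20 (log2 2.90, SE 0.18, adjusted p = 1.8e-09) and in the double mutants (log2 3.19, SE 0.18, adjusted p = 7.5e-10). Compared with p53, Trp53 was also higher in E20 (log2 1.24, SE 0.18, adjusted p = 9.0e-05) and in the double mutants (log2 1.53, SE 0.18, adjusted p = 1.9e-05). Between E20/p53 and E20, Trp53 did not pass (log2 0.29, SE 0.15, adjusted p = 0.13), but it did without E20/p53 replicate 2 (log2 0.39, adjusted p = 0.038), without E20/p53 1 to 3 (log2 0.69) and with a muscle marker covariate (log2 0.17). It turned without E20/p53 4 to 6 (log2 -0.11) and with voom (log2 -0.12), where that set has little weight. The set of E20/p53 4 to 6 held 312 ± 2.65 CPM and the set of 1 to 3 179 ± 10.8 CPM. These levels count the gene's reads and do not tell the alleles apart.

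Pik3ca fell against WT in p53 (log2 -0.35, SE 0.10, adjusted p = 0.007), in E20 (log2 -0.53, SE 0.09, adjusted p = 8.3e-05) and in the double mutants (log2 -0.60, SE 0.09, adjusted p = 2.8e-05). In E20/p53 against p53 it fell as well (log2 -0.24, SE 0.09, adjusted p = 0.0489). That call was lost without any 1 p53 library (adjusted p = 0.106, 0.107 and 0.165) and without E20/p53 replicates 1, 2 or 3 (adjusted p = 0.0914, 0.0807 and 0.0912). Pik3ca did not pass in E20 against p53 (log2 -0.17, SE 0.09, adjusted p = 0.144) or in E20/p53 against E20 (log2 -0.07, SE 0.07, adjusted p = 0.445). Cdkn1a was near 5.07 CPM in WT and rose in p53 (log2 5.46, SE 0.89, adjusted p = 9.8e-05) and in E20 (log2 5.93, SE 0.77, adjusted p = 8.0e-06). In the double mutants Cdkn1a was lower than in E20 (log2 -3.92, SE 0.63, adjusted p = 1.3e-04) and lower than in p53 (log2 -3.45, SE 0.77, adjusted p = 0.00402). The rise of Cdkn1a in E20/p53 over WT (log2 2.01, SE 0.77, adjusted p = 0.0415) was lost when any 1 WT library or any 1 of E20/p53 replicates 4 to 6 was left out. Its adjusted p was then 0.0905, 0.104 and 0.0977 without WT replicates 1 to 3, and 0.0785, 0.079 and 0.0789 without E20/p53 replicates 4 to 6. Cdkn1a did not pass in E20 against p53 (log2 0.47, SE 0.77, adjusted p = 0.693). Mdm2 rose in E20 over WT (log2 1.00, SE 0.21, adjusted p = 7.4e-04), and it was lower in the double mutants than in E20 (log2 -1.25, SE 0.17, adjusted p = 2.5e-05). Mdm2 was lower in E20/p53 than in p53 (log2 -0.77, SE 0.21, adjusted p = 0.0136), which was lost without p53 replicate 2 (log2 -0.71, adjusted p = 0.0659). For Mdm2 in E20 over p53 (log2 0.48, SE 0.21, adjusted p = 0.0922), the call was gained without E20 replicates 4, 5 or 6, with adjusted p of 0.049, 0.047 and 0.0456. In p53 against WT (log2 0.52, SE 0.24, adjusted p = 0.0818) and in E20/p53 against WT (log2 -0.25, SE 0.21, adjusted p = 0.336) Mdm2 did not pass. With whole sets left out, calls were lost for Cdkn1a in E20/p53 over WT without E20/p53 4 to 6 (log2 0.44), and for Mdm2 (log2 -0.64) and Pik3ca (log2 -0.16) in E20/p53 against p53 without E20/p53 1 to 3. In E20/p53 against E20, Pik3ca turned without E20 4 to 6 (log2 0.078) or E20/p53 1 to 3 (log2 0.017), and passed without E20 1 to 3 (log2 -0.22) or with voom (log2 -0.28). In E20 against p53, Pik3ca passed without E20 4 to 6 (log2 -0.32), and with a muscle marker covariate it turned (log2 0.064).

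**Figure D3:**
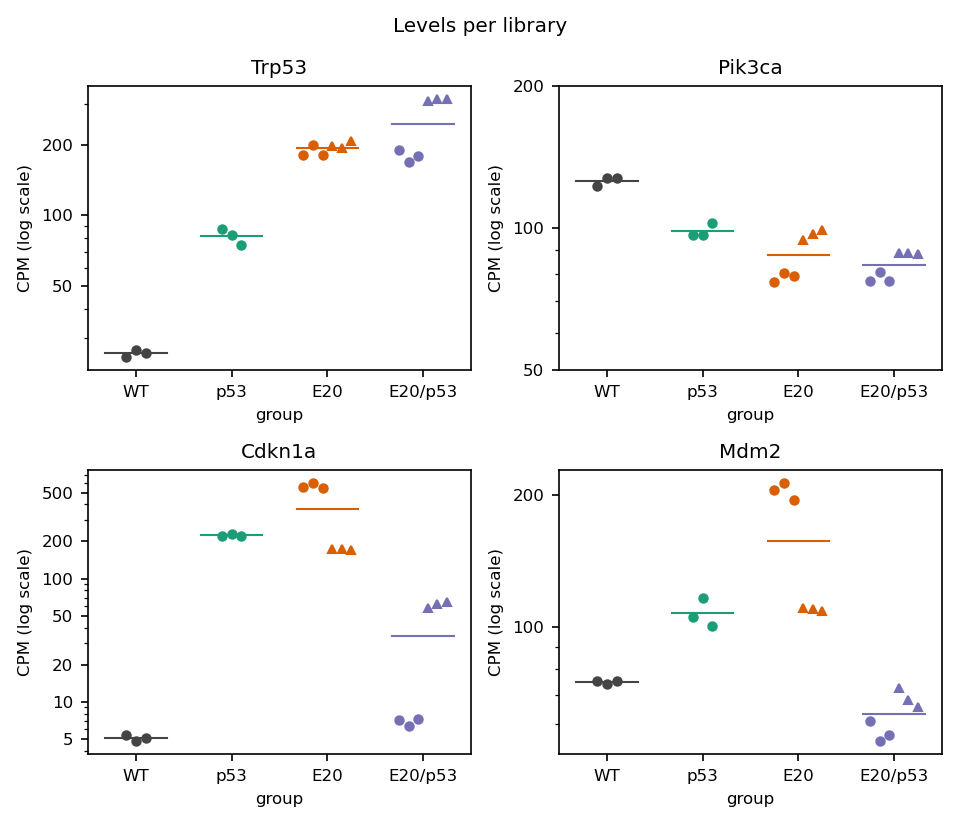
CPM on a log scale (vertical axis) of Trp53, Pik3ca, Cdkn1a and Mdm2 by group (horizontal axis), with 1 point per library, circles for replicates 1 to 3, triangles for replicates 4 to 6, and a line at the group mean. Mean Cdkn1a was 5.07 CPM in WT, 226 in p53, 370 in E20 and 34.2 in E20/p53.

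E20/p53 against E20 asks what a mutant p53 allele adds to mutant PIK3CA in the tongue. The p53 target and interferon response lists were lower in the double mutants at the preset correlation of camera, and neither call held with an estimated one (adjusted p = 0.235 and 0.173). Cyclin G1 (Ccng1) takes part in p53 feedback, Phlda3 blocks AKT at the membrane, and Ephx1 is a detoxifying hydrolase. Ifit3, Oasl2, Oas2, Oas1a and Oas1g encode antiviral proteins that interferon induces. Ccng1 stood at 82.7 ± 9.78 against 351 ± 139 CPM, log2 -1.99, SE 0.20, adjusted p = 1.2e-06 (n = 6 and 6). Phlda3 (69.2 ± 9.04 against 223 ± 63.3 CPM, log2 -1.65, SE 0.15, adjusted p = 3.9e-07) and Ephx1 (85.3 ± 34.7 against 522 ± 135 CPM, log2 -2.68, SE 0.23, adjusted p = 2.3e-07) fell too. Ifit3 fell to 1.81 ± 0.486 against 168 ± 65.2 CPM, log2 -6.43, SE 0.24, adjusted p = 8.5e-12. Oasl2 fell from 284 to 6.24 CPM (log2 -5.39, SE 0.25, adjusted p = 1.4e-10). Oas1a (0.534 ± 0.248 against 91.0 ± 53.9 CPM, adjusted p = 1.2e-09), Oas1g (0.235 ± 0.135 against 54.7 ± 38.9 CPM, adjusted p = 1.1e-08) and Oas2 (0.029 ± 0.0318 against 62.5 ± 54.3 CPM, adjusted p = 1.5e-08) were among the genes with the largest fall, with the interferon-induced Ifi27l2a (0.692 ± 0.61 against 153 ± 78.9 CPM, adjusted p = 4.0e-09). Slfn2, a schlafen gene of immune quiescence, fell as well (0.204 ± 0.119 against 41.3 ± 30.1 CPM, adjusted p = 1.5e-08). Tbx4, a limb and lung transcription factor, was at 0.0198 ± 0.0486 against 14.3 ± 3.46 CPM, adjusted p = 8.2e-12, and the methyltransferase gene Inmt at 0.0103 ± 0.0252 against 9.74 ± 1.49 CPM, adjusted p = 1.2e-12.

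Genes of the sex chromosomes differed, so sex goes with this comparison. Xist was at 0.651 ± 0.233 against 1098 ± 234 CPM, adjusted p = 1.2e-14. The Y genes Eif2s3y, Ddx3y and Kdm5d had 0 reads in E20 and stood at least 2594-fold, at least 2274-fold and at least 789-fold higher in E20/p53, over the groups and against a floor of 3 reads. Uty was at 28.8 ± 11.1 against 0.0113 ± 0.0278 CPM, adjusted p = 1.2e-12. Other large rises were in Hhip, which binds Hedgehog ligands (134 ± 139 against 0.034 ± 0.0569 CPM, adjusted p = 2.5e-06), and Prdm16, a regulator of brown fat fate (13.3 ± 2.51 against 0.17 ± 0.201 CPM, adjusted p = 5.3e-08). The mean of Hhip joins 2 unlike sets, with 261 CPM in E20/p53 1 to 3. The synaptic gene Rims2 (35.6 ± 0.944 CPM in E20/p53 1 to 3 and 2.35 ± 0.191 CPM in E20/p53 4 to 6, against 0.13 ± 0.193 CPM, adjusted p = 2.0e-05) and the receptor gene Gpr153 (42.1 ± 24.0 against 0.632 ± 0.386 CPM, adjusted p = 7.5e-09) rose as well. Of 15235 genes, limma called 3502 higher and 2989 lower, of which 1014 and 1267 differed at least 2-fold. Every E20/p53 library lay above every E20 library for 1714 genes and below for 1712, against chance shares for both directions together of 0.216% over single libraries and 33.3% over sets. Limma on the set means called 0 genes, and 973 had an unadjusted p under 0.05.

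Of 37 gene lists fixed before the data were examined, camera called 11 at its preset correlation. None of these calls held with an estimated correlation, where 3 lists had an unadjusted p under 0.05. The interferon response list had 23 of 23 genes lower (23 adjusted within the list), median log2 -4.37, adjusted p = 9.7e-22 (0.173 with estimated correlation). The p53 target list had 1 of 29 genes higher and 23 lower (1 and 23 adjusted within the list), median log2 -1.29, adjusted p = 1.1e-08 (0.235 with estimated correlation). Lists of proliferation rose by less. Mitotic cell cycle had 16 of 24 genes higher and 1 lower (16 and 1 adjusted within the list), median log2 0.36, adjusted p = 1.1e-04 (0.102 with estimated correlation). The kinase gene Aurka (log2 0.47, SE 0.05, adjusted p = 6.2e-07) and cyclin B1 (Ccnb1, log2 0.56, SE 0.05, adjusted p = 6.9e-07) passed. DNA replication had 13 of 25 genes higher (13 adjusted within the list), median log2 0.22, adjusted p = 0.00439 (0.566 with estimated correlation). Mcm10 (log2 0.74, SE 0.05, adjusted p = 1.5e-08) and the polymerase gene Pole (log2 0.72, SE 0.07, adjusted p = 3.4e-07) passed. Fibroblast genes were lower, with 8 of 10 genes lower (9 adjusted within the list), median log2 -3.48, adjusted p = 7.2e-04 (0.585 with estimated correlation). Decorin (Dcn), a matrix proteoglycan, was at 11.3 ± 4.53 against 136 ± 51.8 CPM, log2 -3.59, SE 0.28, adjusted p = 6.7e-08, and the surface marker Thy1 at 0.0528 ± 0.0835 against 0.504 ± 0.172 CPM, adjusted p = 5.8e-05. Collagens and matrix had 9 of 16 genes lower (9 adjusted within the list), median log2 -1.15, adjusted p = 0.00931 (0.843 with estimated correlation). The basement membrane gene Col4a1 (log2 -0.96, SE 0.08, adjusted p = 1.0e-07) passed. Unfolded protein response had 8 of 15 genes lower (10 adjusted within the list), median log2 -0.72, adjusted p = 5.1e-04 (0.617 with estimated correlation). The isomerase gene Pdia6 (log2 -0.87, SE 0.08, adjusted p = 5.7e-07) passed.

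Oxidative phosphorylation had 13 of 22 genes lower (14 adjusted within the list), median log2 -0.22, adjusted p = 2.9e-04 (0.513 with estimated correlation). The respiratory chain genes Uqcrc2 (log2 -0.58, SE 0.07, adjusted p = 4.3e-06) and Cox5b (log2 -0.77, SE 0.10, adjusted p = 9.8e-06) passed. Hox genes, which carry position along the body axis, had 9 of 15 genes lower (10 adjusted within the list), median log2 -3.27, or -3.60 with genes at 0 reads set to their bound, adjusted p = 0.0129 (0.843 with estimated correlation). Hoxb2 was at 2.13 ± 2.38 against 16.3 ± 2.14 CPM, adjusted p = 0.00144 and Hoxb5 at 0.172 ± 0.191 against 1.89 ± 1.42 CPM, adjusted p = 0.0011. Cholesterol synthesis had 7 of 21 genes lower (7 adjusted within the list), median log2 -0.49, adjusted p = 0.015 (0.872 with estimated correlation). Its gene Insig1, a brake on sterol sensing, was at 34.9 ± 4.93 against 166 ± 73.2 CPM, log2 -2.13, SE 0.23, adjusted p = 2.1e-06, and Fdps (log2 -0.97, SE 0.25, adjusted p = 0.00588) overlapped between the groups. That list's call was lost without E20 replicates 4, 5 or 6 (adjusted p = 0.0537, 0.0524 and 0.0571) and without E20/p53 replicates 4, 5 or 6 (adjusted p = 0.0754, 0.072 and 0.0734). Cytosolic ribosomal proteins had 3 of 24 genes higher and 10 lower (3 and 10 adjusted within the list), median log2 -0.30, adjusted p = 0.0169 (0.843 with estimated correlation). Rps9 was lower (log2 -0.62, SE 0.10, adjusted p = 1.6e-04) and Rps2 was higher (log2 0.66, SE 0.08, adjusted p = 1.2e-05). The call for that list was lost without E20 replicate 2 (adjusted p = 0.0508). With a whole set left out, list calls were lost (with the median log2 then) without E20 1 to 3 for collagens and matrix (-1.06) and cytosolic ribosomal proteins (-0.17). They were lost without E20 4 to 6 for cholesterol synthesis (0.15) and Hox genes (-1.65). They were lost without E20/p53 1 to 3 for collagens and matrix (-0.048), cytosolic ribosomal proteins (0.032), fibroblast (-0.85), Hox genes (-0.80) and unfolded protein response (-0.068). They were lost without E20/p53 4 to 6 for cholesterol synthesis (0.026) and DNA replication (0.23).

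**Figure D4:**
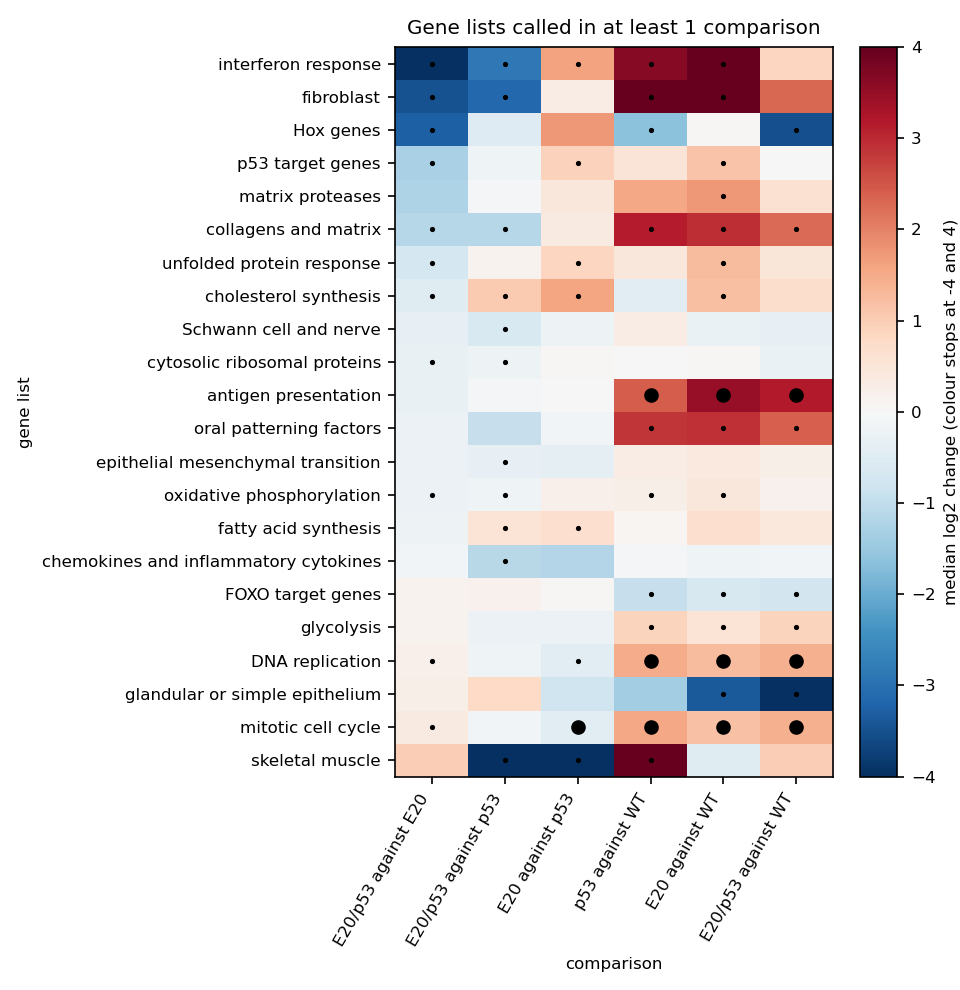
Median log2 change (colour, which stops at -4 and 4) of the 22 gene lists that camera called in at least 1 comparison (vertical axis) in the 6 comparisons (horizontal axis). Small dots mark calls at the preset correlation and large dots those that held with an estimated correlation, which number 10.

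E20/p53 against p53 asks what mutant PIK3CA adds to the mutant p53 allele in the tongue. The skeletal muscle list was lower in the double mutants at the preset correlation, a call that did not hold with an estimated one (adjusted p = 0.615). Myod1 and Myog encode the factors that drive muscle fate, Chrna1 a subunit of the muscle acetylcholine receptor, Mylpf a fast myosin light chain, and Ryr1 the muscle calcium release channel. Myod1 was at 4.73 ± 5.21 against 153 ± 3.84 CPM, adjusted p = 0.00241 (n = 6 and 3), Myog at 4.44 ± 4.89 against 119 ± 6.42 CPM, adjusted p = 0.00418, and Mylpf at 7.17 ± 5.46 against 156 ± 11.8 CPM, log2 -4.89, SE 0.57, adjusted p = 1.4e-05. Ryr1 fell too (3.06 ± 1.21 against 44.2 ± 7.21 CPM, log2 -3.89, SE 0.26, adjusted p = 3.7e-08). Thy1, a surface protein of stromal cells, fell to 0.0528 ± 0.0835 against 125 ± 10.8 CPM, adjusted p = 4.6e-10, and Ptgis, the prostacyclin synthase gene, to 0.0985 ± 0.132 against 47.7 ± 1.63 CPM, adjusted p = 6.9e-07. Lhx8, a jaw patterning factor (0.0103 ± 0.0252 against 13.5 ± 0.91 CPM, adjusted p = 2.2e-07), Iqsec3 (0.0471 ± 0.0753 against 17.3 ± 1.31 CPM, adjusted p = 2.0e-07) and the ribosomal gene Rps4l (0.0103 ± 0.0252 against 11.2 ± 1.63 CPM, adjusted p = 4.1e-10) fell as well. Among the largest rises were Enpp2, which makes lysophosphatidic acid (97.6 ± 43.4 against 3.71 ± 0.698 CPM, log2 4.58, SE 0.41, adjusted p = 8.7e-07), and the ferritin receptor gene Scara5 (43.8 ± 26.7 against 1.39 ± 0.347 CPM, log2 4.68, SE 0.61, adjusted p = 4.2e-05). Tfap2a, an epithelial transcription factor, was at 46.3 ± 44.4 against 0.347 ± 0.0756 CPM, adjusted p = 1.6e-04, and Itgb4, an integrin of hemidesmosomes, at 80.2 ± 83.1 against 1.02 ± 0.121 CPM, adjusted p = 0.00671. Csmd1 (6.03 ± 5.90 against 0.0217 ± 0.0376 CPM, adjusted p = 0.00575) and Cadps (7.21 ± 6.66 against 0.065 ± 0.00197 CPM, adjusted p = 5.0e-04) rose from near 0.

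Chrna1, Casp1 and Pitpnm3 passed narrowly. Chrna1 was at 130 ± 143 against 721 ± 21.4 CPM, adjusted p = 0.0459, and left the threshold without any 1 p53 replicate (0.117, 0.122 and 0.115 for replicates 1 to 3) and without E20/p53 replicates 1, 2 or 3 (0.0878, 0.0869 and 0.0872). The caspase gene Casp1 was at 40.3 ± 2.10 CPM in E20/p53 1 to 3 and 0.244 ± 0.0658 CPM in E20/p53 4 to 6, against 0.0434 ± 0.0752 CPM, adjusted p = 0.0498, and at 0.141, 0.0932 and 0.143 without p53 replicates 1 to 3, and 0.0961, 0.0959 and 0.0957 without E20/p53 replicates 1 to 3. Pitpnm3, a lipid transfer gene, was at 17.2 ± 18.4 against 0.0855 ± 0.074 CPM, adjusted p = 0.0176, and at 0.0842 without p53 replicate 1. Of 15235 genes, limma called 1960 higher and 1964 lower, with 567 and 1014 at least 2-fold. Without p53 replicates 1, 2 or 3 the counts were 1111, 1117 and 1176 higher and 1301, 1214 and 1285 lower. All 6 E20/p53 libraries lay above all 3 p53 libraries for 2417 genes and below for 2532, against chance shares of 2.38% over single libraries and 66.7% over sets. With each set counted once, limma called 0 genes, and 422 had an unadjusted p under 0.05. With a muscle marker covariate Casp1 (2 reads in p53), Pitpnm3 (log2 -1.83), Itgb4 (-0.88), Myod1 (0.16), Chrna1 (5.20) and Myog (0.50) turned. Pitpnm3, Itgb4 and Chrna1 passed that way.

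Camera called 11 of 37 lists, and none held with an estimated correlation, where 3 had an unadjusted p under 0.05. Without E20/p53 replicate 1, camera called 6 lists. Skeletal muscle had 17 of 20 genes lower (19 adjusted within the list), median log2 -4.02, adjusted p = 6.0e-12 (0.615 with estimated correlation). The interferon response had 20 of 23 genes lower (22 adjusted within the list), median log2 -2.85, adjusted p = 2.8e-15 (0.452 with estimated correlation). Ifit3 was at 1.81 ± 0.486 against 35.3 ± 5.31 CPM, adjusted p = 3.8e-08 and Usp18, which removes the interferon-induced ISG15 protein, at 1.39 ± 0.332 against 34.4 ± 2.49 CPM, adjusted p = 2.0e-06. Fibroblast genes had 6 of 10 genes lower (8 adjusted within the list), median log2 -3.14, adjusted p = 9.8e-06 (0.574 with estimated correlation). Dcn (log2 -2.48, SE 0.35, adjusted p = 8.6e-05) and the growth factor receptor gene Pdgfra (58.0 ± 8.68 against 394 ± 8.73 CPM, log2 -2.78, SE 0.36, adjusted p = 4.7e-05) passed. Cholesterol synthesis was higher, with 9 of 21 genes higher (10 adjusted within the list), median log2 1.05, adjusted p = 2.2e-04 (0.858 with estimated correlation). Its gene Hmgcs1 (log2 1.67, SE 0.37, adjusted p = 0.00357) rose. Fatty acid synthesis had 1 of 13 genes higher (1 adjusted within the list), median log2 0.54, adjusted p = 0.0289 (0.858 with estimated correlation), and that gene was the desaturase Scd1 (log2 0.93, SE 0.20, adjusted p = 0.00297).

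The chemokine and cytokine list had 1 of 13 genes higher and 5 lower (1 and 6 adjusted within the list), median log2 -1.10, adjusted p = 0.0258 (0.452 with estimated correlation). Il6 was at 9.75 ± 0.506 against 41.7 ± 4.40 CPM, adjusted p = 1.4e-06 and the monocyte attractant Ccl2 at 159 ± 25.4 against 386 ± 23.8 CPM, adjusted p = 0.00201. Without E20/p53 replicates 4, 5 or 6 its adjusted p was 0.0544, 0.0574 and 0.0568. Epithelial mesenchymal transition had 1 of 17 genes higher and 7 lower (1 and 7 adjusted within the list), median log2 -0.32, adjusted p = 0.0258 (0.858 with estimated correlation), and Twist2, a factor of mesenchymal cells, was at 5.40 ± 0.63 against 22.1 ± 1.89 CPM, adjusted p = 5.9e-07. Collagens and matrix had 3 of 16 genes lower (3 adjusted within the list), median log2 -1.14, adjusted p = 0.0258 (0.858 with estimated correlation). Col4a1 was lower (log2 -1.37, SE 0.10, adjusted p = 5.5e-08). Without E20/p53 replicates 1, 2 or 3 the collagen list had adjusted p of 0.0549, 0.0508 and 0.0551. Without all 3 of them it was called in the other direction (median log2 0.59, adjusted p = 0.0109, within 5.0e-09 to 0.858 over its alternatives), so its fall comes from that set. Cytosolic ribosomal proteins had 1 of 24 genes higher and 6 lower (1 and 6 adjusted within the list), median log2 -0.20, adjusted p = 0.0258 (0.858 with estimated correlation). Rpl3 was lower (log2 -1.12, SE 0.20, adjusted p = 6.6e-04). Oxidative phosphorylation had 6 of 22 genes lower (6 adjusted within the list), median log2 -0.19, adjusted p = 0.0417 (0.858 with estimated correlation). Cytochrome c (Cycs, log2 -0.52, SE 0.07, adjusted p = 5.9e-05) passed. Schwann cell and nerve genes had 3 of 5 genes lower (3 adjusted within the list), median log2 -0.61, adjusted p = 0.0417 (0.858 with estimated correlation). The myelin gene Mbp was at 1.37 ± 0.747 against 3.72 ± 0.166 CPM, adjusted p = 0.00499. Without E20/p53 replicate 1, adjusted p was 0.0506 for the fatty acid, transition, oxidative phosphorylation, ribosomal and Schwann cell lists. Without p53 replicate 2 it was 0.148 for oxidative phosphorylation and 0.0622 for the ribosomal and Schwann cell lists. Oxidative phosphorylation also left the threshold without E20/p53 replicates 2, 4 and 5 (0.0507, 0.0511 and 0.0591), and the Schwann cell list without replicates 5 and 6 (0.0533 and 0.0522). With a whole set left out, list calls were lost (with the median log2 then) without E20/p53 1 to 3 for cholesterol synthesis (0.38), cytosolic ribosomal proteins (0.031), epithelial mesenchymal transition (-0.10), fatty acid synthesis (0.15), fibroblast (-1.69), oxidative phosphorylation (-0.045) and Schwann cell and nerve (-0.59). They were lost without E20/p53 4 to 6 for chemokines and cytokines (-0.55), oxidative phosphorylation (-0.23) and Schwann cell and nerve (-0.75).

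E20 against p53 sets the PIK3CA allele beside the p53 allele in the tongue. The skeletal muscle list was lower in E20 at the preset correlation, which did not hold with an estimated one (adjusted p = 0.546). Mymk encodes the factor that fuses myoblasts, Myh3 the embryonic myosin, and Mybph a myosin-binding protein. Myod1 was at 0.121 ± 0.0654 against 153 ± 3.84 CPM, adjusted p = 2.3e-04 (n = 6 and 3), Myog at 0.192 ± 0.197 against 119 ± 6.42 CPM, adjusted p = 4.7e-04, and Mymk at 0.111 ± 0.0941 against 71.8 ± 2.93 CPM, adjusted p = 1.4e-04. Myh3 (0.0224 ± 0.0347 against 36.1 ± 0.536 CPM, adjusted p = 1.0e-04) and Mybph (0.0227 ± 0.0352 against 41.0 ± 2.84 CPM, adjusted p = 3.2e-05) were near 0 in E20. Sex also goes with this comparison. Xist was at 1098 ± 234 against 0.172 ± 0.0693 CPM, adjusted p = 4.1e-14, and the Y genes Eif2s3y, Ddx3y and Kdm5d, with 0 reads in E20, were at least 2888-fold, at least 2395-fold and at least 896-fold higher in p53 over the groups. Among the rises, Gbp2b encodes an interferon-induced GTPase (37.9 ± 16.6 against 0.105 ± 0.182 CPM, adjusted p = 1.0e-04), Mmp13 a collagenase (265 ± 283 against 0.695 ± 0.175 CPM, adjusted p = 0.00182), and Chrdl1 an inhibitor of bone morphogenetic proteins (139 ± 78.5 against 1.32 ± 0.0591 CPM, log2 6.43, SE 0.43, adjusted p = 2.1e-08). Cyp2f2 (10.8 ± 3.53 against 0.0868 ± 0.0378 CPM, adjusted p = 0.00244), Inmt (9.74 ± 1.49 against 0.065 ± 0.00197 CPM, adjusted p = 2.2e-10), the epithelial factor gene Ehf (9.48 ± 2.11 against 0.151 ± 0.164 CPM, adjusted p = 6.6e-04) and the noncoding RNA Mira (11.2 ± 9.45 against 0.0853 ± 0.0959 CPM, adjusted p = 5.6e-04) rose as well. Limma called 2205 of 15235 genes higher and 2504 lower, with 877 and 999 at least 2-fold. All 6 E20 libraries lay above all 3 p53 libraries for 3311 genes and below for 3622, against chance shares of 2.38% over single libraries and 66.7% over sets. From the 6 set means, limma called 0 genes, and 629 had an unadjusted p under 0.05. With a muscle marker covariate Cyp2f2 turned and passed (log2 -1.33).

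Camera called 8 of 37 lists in E20 against p53, and 1, mitotic cell cycle, held with an estimated correlation. It had 15 of 24 genes lower (16 adjusted within the list), median log2 -0.47, adjusted p = 1.3e-07 (0.0144 with estimated correlation). Aurka (log2 -0.75, SE 0.06, adjusted p = 7.2e-08) and the spindle motor gene Kif11 (log2 -0.62, SE 0.06, adjusted p = 7.0e-07) were lower. DNA replication had 17 of 25 genes lower (18 adjusted within the list), median log2 -0.41, adjusted p = 1.1e-06 (0.247 with estimated correlation). Mcm10 (log2 -0.68, SE 0.06, adjusted p = 9.8e-07) and the origin licensing gene Cdc6 (log2 -0.66, SE 0.12, adjusted p = 4.2e-04) passed. Skeletal muscle had 17 of 20 genes lower (19 adjusted within the list), median log2 -4.65, or -4.88 with genes at 0 reads set to their bound, adjusted p = 1.4e-11 (0.546 with estimated correlation). Mylpf (log2 -7.00, SE 0.57, adjusted p = 2.3e-07) and Ryr1 (log2 -4.75, SE 0.26, adjusted p = 3.0e-09) passed. Genes of p53 targets were higher in E20, with 15 of 29 genes higher (21 adjusted within the list), median log2 0.94, adjusted p = 4.0e-07 (0.439 with estimated correlation). Ephx1 (522 ± 135 against 72.0 ± 2.29 CPM, log2 2.82, SE 0.29, adjusted p = 2.5e-06) and Bbc3, which encodes the death factor PUMA (11.6 ± 2.70 against 4.55 ± 0.242 CPM, log2 1.30, SE 0.18, adjusted p = 4.5e-05), rose. The interferon response had 19 of 23 genes higher (19 adjusted within the list), median log2 1.60, adjusted p = 1.2e-08 (0.546 with estimated correlation). Ifit3 (log2 2.16, SE 0.29, adjusted p = 3.6e-05) passed. Cholesterol synthesis had 18 of 21 genes higher (20 adjusted within the list), median log2 1.57, adjusted p = 1.2e-08 (0.665 with estimated correlation). The mevalonate pathway genes Mvk (log2 1.72, SE 0.24, adjusted p = 4.6e-05) and Fdps (log2 1.97, SE 0.31, adjusted p = 1.6e-04) passed. Fatty acid synthesis had 6 of 13 genes higher (7 adjusted within the list), median log2 0.68, adjusted p = 0.00165 (0.698 with estimated correlation). Scd1 (log2 1.28, SE 0.20, adjusted p = 1.4e-04) passed. The unfolded protein response had 7 of 15 genes higher (10 adjusted within the list), median log2 0.85, adjusted p = 7.1e-05 (0.546 with estimated correlation). Pdia6 (log2 0.96, SE 0.10, adjusted p = 3.8e-06) and the chaperone partner Sdf2l1 (log2 1.48, SE 0.19, adjusted p = 2.5e-05) passed. With a whole set left out, list calls were lost (with the median log2 then) without E20 4 to 6 for fatty acid synthesis (0.25).

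p53 against WT sets tongue with the p53 allele beside wild type esophagus, so tissue and allele go together here and in the other comparisons with WT. The muscle, collagen and fibroblast lists were higher in the p53 libraries at the preset correlation, and none of these calls held with an estimated one (adjusted p = 0.66, 0.665 and 0.477). M-cadherin (Cdh15), MyoD (Myod1) and desmin (Des) mark muscle cells and their precursors, Igfbp5 binds insulin-like growth factors, and H19 is an imprinted noncoding RNA of fetal tissue and regenerating muscle. Cdh15 was at 347 ± 7.13 against 0.02 ± 0.0347 CPM, adjusted p = 7.0e-05 (n = 3 and 3), Des at 743 ± 40.0 against 0.258 ± 0.0626 CPM, adjusted p = 0.00408, and H19 at 9993 ± 616 against 4.10 ± 1.36 CPM, adjusted p = 0.00172. Myod1 had 0 reads in WT and stood at least 2560-fold higher over the group. Igfbp5 (780 ± 37.5 against 0.18 ± 0.0069 CPM, adjusted p = 1.3e-06), podoplanin (Pdpn, 407 ± 24.8 against 0.101 ± 0.0736 CPM, adjusted p = 1.1e-13), Srpx2 (283 ± 12.1 against 0.0806 ± 0.0377 CPM, adjusted p = 4.7e-07) and Tmem47 (179 ± 14.5 against 0.02 ± 0.0347 CPM, adjusted p = 6.3e-09) rose from near 0. Among the lower genes, Krt18 was at 0.0217 ± 0.0376 against 228 ± 8.18 CPM, adjusted p = 7.6e-05, the secreted inhibitor Wfdc2 at 0.13 ± 0.173 against 538 ± 8.06 CPM, adjusted p = 0.0021, and Perp, a desmosome gene that p53 family members activate, at 0.368 ± 0.0949 against 226 ± 6.97 CPM, adjusted p = 0.00618. The choline transporter gene Slc5a7, the position gene Hoxc5, the kidney and ear factor gene Pax2 and the receptor gene Gpr149 had 0 reads in p53. They were at least 5806-fold, at least 574-fold, at least 543-fold and at least 514-fold higher in WT. Casp1 was at 0.0434 ± 0.0752 against 55.8 ± 3.09 CPM, adjusted p = 0.00194. Limma called 4459 of 15235 genes higher and 3800 lower, with 2361 and 2078 at least 2-fold. All p53 libraries lay above all WT libraries for 6588 genes and below for 5929, against chance shares of 10% over single libraries and 100% over the 2 sets. Limma on the set means called 1 gene, and 1627 genes had an unadjusted p under 0.05. With a muscle marker covariate H19 (log2 -2.13), Des (-4.20), Wfdc2 (2.67), Casp1 (2 reads in p53) and Perp (1.59) turned. Des and Wfdc2 passed that way.

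Camera called 12 of 37 lists in p53 against WT. With an estimated correlation 3 held, mitotic cell cycle, DNA replication and antigen presentation. Mitotic cell cycle had 24 of 24 genes higher (24 adjusted within the list), median log2 1.56, adjusted p = 6.5e-15 (3.5e-04 with estimated correlation). Kif11 (log2 1.95, SE 0.06, adjusted p = 1.1e-12) and the survivin gene Birc5 (log2 2.20, SE 0.09, adjusted p = 2.0e-11) passed. DNA replication had 25 of 25 genes higher (25 adjusted within the list), median log2 1.49, adjusted p = 3.5e-14 (0.00891 with estimated correlation). The helicase gene Mcm5 (log2 2.21, SE 0.08, adjusted p = 3.6e-12) and thymidine kinase (Tk1, log2 2.39, SE 0.13, adjusted p = 6.8e-10) passed. Antigen presentation had 9 of 12 genes higher (9 adjusted within the list), median log2 2.43, adjusted p = 4.9e-06 (0.00213 with estimated correlation). Psmb8, an immunoproteasome gene, was at least 549-fold higher than in WT, which held 0 reads, and the peptide transporter gene Tap1 was at 26.6 ± 1.07 against 0.242 ± 0.113 CPM, log2 6.53, SE 0.20, adjusted p = 3.1e-13. The interferon response had 20 of 23 genes higher (20 adjusted within the list), median log2 3.65, adjusted p = 5.8e-09 (0.398 with estimated correlation). Isg15 (86.5 ± 7.10 against 1.74 ± 0.373 CPM, log2 5.61, SE 0.40, adjusted p = 1.1e-08) and Oas1a (24.6 ± 1.51 against 0.0192 ± 0.0332 CPM, adjusted p = 4.9e-09) passed. Skeletal muscle had 20 of 20 genes higher (20 adjusted within the list), median log2 4.60, adjusted p = 5.0e-06 (0.66 with estimated correlation). Mylpf (log2 6.35, SE 0.66, adjusted p = 8.4e-07) and Ryr1 (log2 3.83, SE 0.30, adjusted p = 4.1e-08) passed. Collagens and matrix had 14 of 16 genes higher (15 adjusted within the list), median log2 3.14, adjusted p = 1.8e-04 (0.665 with estimated correlation). Col6a2 (log2 3.94, SE 0.52, adjusted p = 1.1e-05) and the collagen cross-linking gene Lox (log2 3.01, SE 0.43, adjusted p = 2.7e-05) passed. Fibroblast genes had 8 of 10 genes higher (9 adjusted within the list), median log2 5.25, adjusted p = 8.2e-04 (0.477 with estimated correlation). Pdgfra (log2 5.55, SE 0.42, adjusted p = 2.5e-08) and Dcn (log2 4.66, SE 0.40, adjusted p = 1.0e-07) passed.

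Glycolysis had 10 of 16 genes higher (11 adjusted within the list), median log2 0.90, adjusted p = 0.00214 (0.665 with estimated correlation). The enolase gene Eno1 (log2 1.86, SE 0.12, adjusted p = 5.5e-09) passed. Oxidative phosphorylation had 8 of 22 genes higher and 1 lower (8 and 1 adjusted within the list), median log2 0.24, adjusted p = 0.0492 (0.677 with estimated correlation). Cycs (log2 1.57, SE 0.08, adjusted p = 2.6e-10) passed. That list's call was lost without WT replicates 1 or 2 or p53 replicate 2 (adjusted p = 0.0569, 0.0699 and 0.0962). FOXO target genes, which PI3-kinase signalling holds down, had 12 of 17 genes lower (12 adjusted within the list), median log2 -0.93, adjusted p = 0.00233 (0.398 with estimated correlation). Between tongue groups camera did not call this list. The PI3-kinase inhibitor gene Pik3ip1 (log2 -3.93, SE 0.43, adjusted p = 1.5e-06) and the insulin receptor substrate gene Irs2 (log2 -2.25, SE 0.26, adjusted p = 2.6e-06) fell. Oral patterning factors had 8 of 14 genes higher and 1 lower (8 and 1 adjusted within the list), median log2 2.87, adjusted p = 0.0107 (0.0635 with estimated correlation). Msx1, which patterns mouth and teeth, had 0 reads in WT and was at least 31.5-fold higher. Hox genes had 4 of 15 genes lower (4 adjusted within the list), median log2 -1.65, adjusted p = 0.0458 (0.839 with estimated correlation).

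E20 against WT sets tongue with the PIK3CA allele beside wild type esophagus. The collagen, fibroblast and interferon response lists were higher in E20 at the preset correlation, and none of these calls held with an estimated one (adjusted p = 0.574, 0.574 and 0.198). Nid2 encodes a basement membrane protein, Grb10 is an imprinted brake on insulin signalling, and Iigp1 is an interferon-induced GTPase. Nid2 was at 946 ± 179 against 0.295 ± 0.168 CPM, adjusted p = 9.2e-10 (n = 6 and 3) and Igfbp5 at 1875 ± 1157 against 0.18 ± 0.0069 CPM, adjusted p = 7.1e-08. Grb10 (279 ± 7.22 against 0.0207 ± 0.0358 CPM, adjusted p = 2.4e-10), Iigp1 (166 ± 46.1 against 0.02 ± 0.0347 CPM, adjusted p = 5.5e-11), Tmem47 (176 ± 32.4 against 0.02 ± 0.0347 CPM, adjusted p = 7.3e-10) and Pdpn (470 ± 176 against 0.101 ± 0.0736 CPM, adjusted p = 1.0e-14) rose from near 0. Simple epithelial keratins fell, with Krt18 at 0.0113 ± 0.0278 against 228 ± 8.18 CPM, adjusted p = 1.3e-05 and its partner Krt8 at 0.0114 ± 0.0278 against 41.5 ± 0.785 CPM, adjusted p = 2.1e-10. Slc5a7 (0.0292 ± 0.0716 against 377 ± 29.4 CPM, adjusted p = 1.1e-13), Wfdc2 (0.149 ± 0.135 against 538 ± 8.06 CPM, adjusted p = 7.3e-04), Hhip (0.034 ± 0.0569 against 124 ± 5.10 CPM, adjusted p = 1.8e-06) and Hoxc4 (0.0679 ± 0.0863 against 66.7 ± 1.78 CPM, adjusted p = 9.3e-09) fell as well. The peptide hormone gene Cck and the factor gene Pax2 had 0 reads in E20 and were at least 1533-fold and at least 1069-fold higher in WT. Limma called 4412 of 15235 genes higher and 4016 lower, with 2044 and 2110 at least 2-fold. All 6 E20 libraries lay above all 3 WT libraries for 5144 genes and below for 4654, against chance shares of 2.38% over single libraries and 66.7% over sets. With each set counted once, limma called 8 genes, Tap1 and Pdpn among them, and 2073 genes had an unadjusted p under 0.05.

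Camera called 15 of 37 lists in E20 against WT, and the same 3 lists as in p53 against WT held with an estimated correlation. Mitotic cell cycle had 24 of 24 genes higher (24 adjusted within the list), median log2 1.17, adjusted p = 9.5e-12 (0.00142 with estimated correlation). Kif11 (log2 1.33, SE 0.06, adjusted p = 1.4e-11) and the mitotic kinase gene Plk1 (log2 1.70, SE 0.07, adjusted p = 1.6e-11) passed. DNA replication had 23 of 25 genes higher (23 adjusted within the list), median log2 1.27, adjusted p = 3.3e-10 (0.0351 with estimated correlation). Mcm5 (log2 1.82, SE 0.07, adjusted p = 3.7e-12) and Tk1 (log2 2.01, SE 0.12, adjusted p = 5.7e-10) passed. Antigen presentation had 9 of 12 genes higher (9 adjusted within the list), median log2 3.48, adjusted p = 1.5e-05 (0.00322 with estimated correlation). Tap1 (log2 7.39, SE 0.17, adjusted p = 7.2e-15) and Psmb9 (7.05 ± 1.61 against 0.0414 ± 0.0717 CPM, adjusted p = 8.8e-11) passed. The interferon response had 23 of 23 genes higher (23 adjusted within the list), median log2 5.74, adjusted p = 1.3e-13 (0.198 with estimated correlation). Isg15 was at 267 ± 52.7 against 1.74 ± 0.373 CPM, log2 7.21, SE 0.34, adjusted p = 5.7e-11 and Ifit3 at 168 ± 65.2 against 2.63 ± 0.236 CPM, log2 5.86, SE 0.29, adjusted p = 8.7e-11. The p53 target list had 19 of 29 genes higher and 3 lower (21 and 3 adjusted within the list), median log2 1.14, adjusted p = 1.8e-04 (0.412 with estimated correlation). Ccng1 (log2 2.23, SE 0.25, adjusted p = 1.5e-06) and Phlda3 (log2 1.99, SE 0.19, adjusted p = 1.9e-07) passed. The unfolded protein response had 13 of 15 genes higher and 1 lower (13 and 1 adjusted within the list), median log2 1.25, adjusted p = 0.00163 (0.526 with estimated correlation). Sdf2l1 (log2 2.71, SE 0.19, adjusted p = 6.4e-09) and Pdia6 (log2 0.98, SE 0.10, adjusted p = 6.7e-07) passed. Cholesterol synthesis had 16 of 21 genes higher and 1 lower (16 and 1 adjusted within the list), median log2 1.21, adjusted p = 0.0076 (0.768 with estimated correlation). Mvk (log2 2.19, SE 0.24, adjusted p = 1.0e-06) and Insig1 (log2 1.69, SE 0.28, adjusted p = 9.5e-05) passed.

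Collagens and matrix had 14 of 16 genes higher (14 adjusted within the list), median log2 2.94, adjusted p = 1.7e-04 (0.574 with estimated correlation). Col6a2 was at 522 ± 42.8 against 13.6 ± 1.36 CPM, log2 5.26, SE 0.45, adjusted p = 6.3e-08. Fibroblast genes had 7 of 10 genes higher (7 adjusted within the list), median log2 4.71, adjusted p = 0.0103 (0.574 with estimated correlation). Dcn (log2 5.78, SE 0.35, adjusted p = 9.5e-10) passed. Matrix proteases had 6 of 12 genes higher (6 adjusted within the list), median log2 1.74, adjusted p = 0.0457 (0.198 with estimated correlation). The membrane protease gene Mmp14 (log2 1.39, SE 0.11, adjusted p = 2.4e-08) passed. That call was lost without WT replicate 3 (adjusted p = 0.0513) and without E20 replicates 4, 5 or 6 (0.0697, 0.0608 and 0.0575). Oxidative phosphorylation had 15 of 22 genes higher (16 adjusted within the list), median log2 0.44, adjusted p = 0.00167 (0.423 with estimated correlation). Cycs (log2 1.23, SE 0.07, adjusted p = 5.4e-10) passed. Glycolysis had 6 of 16 genes higher (6 adjusted within the list), median log2 0.54, adjusted p = 0.0163 (0.743 with estimated correlation). Eno1 (log2 1.85, SE 0.11, adjusted p = 6.5e-10) passed. FOXO target genes had 1 of 17 genes higher and 8 lower (1 and 8 adjusted within the list), median log2 -0.63, adjusted p = 0.0128 (0.412 with estimated correlation). Irs2 (log2 -2.79, SE 0.22, adjusted p = 3.0e-08) and the receptor gene Erbb3 (0.065 ± 0.057 against 2.13 ± 0.355 CPM, adjusted p = 9.2e-06) passed. Oral patterning factors had 8 of 14 genes higher and 3 lower (9 and 4 adjusted within the list), median log2 2.94, or 3.42 with genes at 0 reads set to their bound, adjusted p = 0.0217 (0.129 with estimated correlation). Msx1 was at least 36.6-fold higher than the 0 reads of WT. Glandular or simple epithelium had 4 of 7 genes lower (4 adjusted within the list), median log2 -3.34, adjusted p = 0.0128 (0.198 with estimated correlation). Krt7 was at 0.415 ± 0.371 against 3.34 ± 0.841 CPM, adjusted p = 0.00377. With a whole set left out, list calls were lost (with the median log2 then) without E20 4 to 6 for cholesterol synthesis (0.58), glandular or simple epithelium (-2.66), glycolysis (0.099) and matrix proteases (0.69).

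E20/p53 against WT sets tongue with both alleles beside wild type esophagus. The mitotic cell cycle and DNA replication lists were higher in the double mutants and held with an estimated correlation. Slc14a1 encodes a urea transporter, and Padi4 an enzyme that turns arginine into citrulline. Grb10 (661 ± 548 against 0.0207 ± 0.0358 CPM, adjusted p = 1.6e-10, n = 6 and 3), Pdpn (131 ± 7.08 against 0.101 ± 0.0736 CPM, adjusted p = 9.9e-14), Tmem47 (65.2 ± 54.8 against 0.02 ± 0.0347 CPM, adjusted p = 1.1e-08) and Srpx2 (158 ± 156 against 0.0806 ± 0.0377 CPM, adjusted p = 8.1e-07) rose from near 0. Psmb8 and the Y genes Eif2s3y and Ddx3y had 0 reads in WT and were at least 510-fold, at least 1432-fold and at least 1256-fold higher. Slc14a1 (0.155 ± 0.11 against 71.8 ± 3.37 CPM, adjusted p = 2.0e-11), Padi4 (0.151 ± 0.17 against 49.2 ± 3.29 CPM, adjusted p = 1.5e-07) and Rps4l (0.0103 ± 0.0252 against 36.0 ± 3.27 CPM, adjusted p = 2.5e-12) fell. Hoxc4 was at 0.139 ± 0.149 against 66.7 ± 1.78 CPM, adjusted p = 2.1e-08, Hoxc5 at 0.115 ± 0.156 against 37.3 ± 1.62 CPM, adjusted p = 1.1e-08, and Krt18 at 4.46 ± 4.89 against 228 ± 8.18 CPM, adjusted p = 4.1e-04. Cck, with 0 reads in the double mutants, was at least 1712-fold higher in WT. Limma called 4041 of 15235 genes higher and 3292 lower, with 1668 and 1592 at least 2-fold. All 6 E20/p53 libraries lay above all 3 WT libraries for 4066 genes and below for 3631, against chance shares of 2.38% over single libraries and 66.7% over sets. From the 6 set means, limma called 1 gene, and 1574 genes had an unadjusted p under 0.05.

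Camera called 9 of 37 lists in E20/p53 against WT, and mitotic cell cycle, DNA replication and antigen presentation held with an estimated correlation. Mitotic cell cycle had 24 of 24 genes higher (24 adjusted within the list), median log2 1.43, adjusted p = 7.7e-17 (1.8e-04 with estimated correlation). Kif11 (log2 1.63, SE 0.06, adjusted p = 1.3e-12) and Birc5 (140 ± 2.60 against 37.6 ± 0.69 CPM, log2 1.89, SE 0.08, adjusted p = 2.0e-11) passed. DNA replication had 25 of 25 genes higher (25 adjusted within the list), median log2 1.43, adjusted p = 7.4e-15 (0.00732 with estimated correlation). Mcm5 (log2 2.22, SE 0.07, adjusted p = 3.5e-13) passed. Antigen presentation had 8 of 12 genes higher (8 adjusted within the list), median log2 3.18, adjusted p = 3.6e-06 (0.00172 with estimated correlation). Tap1 (18.3 ± 1.71 against 0.242 ± 0.113 CPM, log2 5.99, SE 0.17, adjusted p = 1.1e-13) passed. Hox genes had 6 of 15 genes lower (6 adjusted within the list), median log2 -3.50, adjusted p = 0.00418 (0.864 with estimated correlation). Hoxb2 was at 2.13 ± 2.38 against 15.7 ± 1.59 CPM, adjusted p = 0.0053. FOXO target genes had 10 of 17 genes lower (11 adjusted within the list), median log2 -0.73, adjusted p = 0.0105 (0.446 with estimated correlation). Irs2 (log2 -2.08, SE 0.22, adjusted p = 1.2e-06) and the insulin receptor gene Insr (log2 -0.84, SE 0.15, adjusted p = 2.9e-04) passed. Glycolysis had 12 of 16 genes higher (12 adjusted within the list), median log2 0.90, adjusted p = 0.0111 (0.867 with estimated correlation). Pgam1 (log2 1.28, SE 0.09, adjusted p = 1.2e-08) and lactate dehydrogenase (Ldha, log2 1.11, SE 0.15, adjusted p = 1.8e-05) passed. Oral patterning factors had 8 of 14 genes higher and 2 lower (8 and 2 adjusted within the list), median log2 2.39, adjusted p = 0.0157 (0.0703 with estimated correlation). Msx1 was at least 15.2-fold higher than the 0 reads of WT. Glandular or simple epithelium had 5 of 7 genes lower (5 adjusted within the list), median log2 -4.16, adjusted p = 0.0142 (0.183 with estimated correlation). Krt8 was at 0.189 ± 0.193 against 41.5 ± 0.785 CPM, adjusted p = 2.2e-09. Collagens and matrix had 10 of 16 genes higher (10 adjusted within the list, with 1 lower), median log2 2.27, adjusted p = 0.0275 (0.942 with estimated correlation). Col6a2 (log2 3.84, SE 0.45, adjusted p = 2.8e-06) and periostin (Postn, 920 ± 835 against 2.67 ± 0.751 CPM, adjusted p = 7.8e-06) passed. Without E20/p53 replicate 5 the collagen list had an adjusted p of 0.0573. With a whole set left out, list calls were lost (with the median log2 then) without E20/p53 1 to 3 for glycolysis (0.42), Hox genes (-0.14) and oral patterning factors (2.35). They were lost without E20/p53 4 to 6 for collagens and matrix (0.61) and FOXO target genes (-0.49).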

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

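The tests of a swap of libraries, of the same cell types in other proportions, of one library set alone and of keratin genes not counted were chosen after the result was seen. In E20 and E20/p53, 181 values were examined for a library far from the other 5 of its group, a check by which chance marks about 1 in 20 groups, and 0 had one. Each of these groups holds 2 sets of 3 libraries, which leaves little room for such a mark.

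Other splits of the same libraries were counted for each comparison. For genes called in p53 against WT and for its gene lists, the 10 splits are too few for a share under 0.05. The real split gave 8259 genes and 12 lists and the highest other 0 genes and 11 lists, and 1 split reached the real value in each case. For genes, few splits called as many as the real one in the other 5 comparisons. These were E20 against WT (1 of 84 splits, real 8428, highest other 3543), E20/p53 against WT (2 of 84, real 7333, highest other 8180), E20/p53 against E20 (1 of 100 drawn from 462, real 6491, highest other 5806), E20/p53 against p53 (3 of 84, real 3924, highest other 9549) and E20 against p53 (1 of 84, real 4709, highest other 4514). Each highest other split in these 5 comparisons follows the sets of 3 libraries. In E20/p53 against p53 it puts E20/p53 1 to 3 apart and calls far more genes than the real split, which points to a structure of the samples. So a low share excludes a random grouping of single libraries and does not tell an allele from a set. For gene lists chance cannot be excluded, in E20 against WT (27 of 84 splits, real 15, highest other 19), E20/p53 against WT (40 of 84, real 9, highest other 13), E20/p53 against E20 (48 of 100, real 11, highest other 18), E20/p53 against p53 (23 of 84, real 11, highest other 13) and E20 against p53 (57 of 84, real 8, highest other 19).

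E20/p53 libraries 1 to 3 stand apart from 4 to 6. A difference in sequencing depth is argued against by the 6 libraries thinned to about 14592000 reads each, where the mean correlation was 0.861 between the sets and 0.993 within them. A swap of single libraries with the WT group is argued against by Hoxc4, Hoxc5 and Hoxc6, which in libraries 1 to 3 reach 0.0428% of their WT level. It is also argued against by 0 Y gene reads in WT. An exchange of all WT libraries for all of libraries 1 to 3 could leave these values as they are, so it stays open. The same cell types in other proportions stay open, since 16 of 2676 genes at 100 CPM or more in 4 to 6 were under 1% of that in 1 to 3, and 12 of 2453 the other way, but these are the pattern's own extremes under an assumed profile per cell type. Different tumours, animals, cultures or cell types, a library batch and a swap with samples outside this study stay open and untested, and no biological explanation was tested.

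Interferon response transcripts were higher in E20 than in the double mutants. One library set alone as the source is argued against by the list median, which was -2.83 in the set pair nearest to 0 of the 4. Macrophages among the E20 cells are argued against by C1qa, C1qb and C1qc, at 0 CPM in all 6 E20 libraries. The scaling is argued against by a median of -4.34 to -4.40 under 3 other scalings. The double mutants were also lower than p53 (20 of 23 genes, median log2 -2.85), and E20 was higher than p53 (median 1.60). The p53 allele, sex, animal, batch and a joint effect of both alleles stay open as untested.

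Keratin transcripts were near 0 in p53, E20 4 to 6 and E20/p53 4 to 6, although all libraries are labelled squamous epithelium, and Krt5 was also near 0 in WT (0.0784 CPM, with Krt14 at 13.4 CPM). Keratin genes not counted in this table are argued against by 3 libraries with at least 50 CPM of both Krt5 and Krt14. Whole tissue in which stroma outweighs epithelium is argued against by the sum of Pecam1, Cdh5 and Ptprc, which was at most 3.25 CPM in these 3 sets, since whole stroma brings vessels and leukocytes. Cells of another kind, loss of keratin expression and a wrong label stay open as untested, and no biological explanation was tested.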

How the results depend on the processing

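The tests with TMM factors, with log2 of CPM plus 1, with 6 set means and without a whole set of libraries were chosen after the data had been seen. Of 228 named gene results, 227 kept direction and side of the threshold with median-of-ratios factors, 227 with TMM factors and 226 with log2 of CPM plus 1, and the others kept their direction. Counts of called genes stayed within 1.5 times those reported under these 3 alternatives, under upper quartile factors, without a filter and with a filter at 5 CPM. Upper quartile factors moved the median log2 change of all genes in E20 against WT from 0.037 to -0.066. The planned runs with DESeq2 were not run, since count models were kept to deposited counts, although reads can be read back from the log2 values.

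A demand for at least a 2-fold change leaves fewer genes by its construction: 2361 higher and 2078 lower in p53 against WT, 2044 higher and 2110 lower in E20 against WT, 1668 higher and 1592 lower in E20/p53 against WT, 1014 higher and 1267 lower in E20/p53 against E20, 567 higher and 1014 lower in E20/p53 against p53 and 877 higher and 999 lower in E20 against p53. With voom and sample quality weights, on the reads behind the log2 values, limma called 5931 lower in p53 against WT, 5350 lower in E20/p53 against WT, 6171 higher and 5451 lower in E20/p53 against E20, 5960 higher and 5902 lower in E20/p53 against p53 and 5213 higher and 5516 lower in E20 against p53. Under voom, Trp53 (-0.12) reversed and Pik3ca (-0.28) passed in E20/p53 against E20, and Cdkn1a (-0.27) reversed in E20 against p53. Voom weights were at most 0.242 in a set each of E20 and E20/p53. The 2 compared groups alone gave 5880 lower in p53 against WT, with set gaps out of the residual.

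Replicate numbers were also used as a block, although nothing in the labels says that equal numbers belong together. Correlation between same-numbered libraries, after group means were removed, was -0.0543 to 0.0744, which gives no sign of pairing. With the block, counts were 5806 lower in p53 against WT, 6225 higher and 5575 lower in E20/p53 against WT, 5939 higher and 5995 lower in E20/p53 against p53 and 5001 higher and 5208 lower in E20 against p53. Libraries with numbers in only 1 of the groups drop out of this fit, which leaves 1 set per group in comparisons with WT or p53. In E20 against p53, Pik3ca (-0.32) then passed and camera called 15 lists. Over the comparisons, 12 lists and 1 named gene lost their call with the block, and 5 named genes gained it.

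A skeletal muscle marker score as a covariate moved counts to 5260 higher and 4579 lower in E20/p53 against E20, 3851 higher and 3174 lower in E20/p53 against p53 and 4479 higher and 4267 lower in E20 against p53. With it, H19 (-2.13), Des (-4.20), Wfdc2 (2.67), Casp1 (0.61), Perp (1.59), the collagens and matrix list (-0.16) and the fibroblast list (-0.21) in p53 against WT, Casp1 (-2.67), Pitpnm3 (-1.83), Itgb4 (-0.88), Myod1 (0.16), Chrna1 (5.20), Myog (0.50), the cholesterol synthesis list (-0.002), the fatty acid synthesis list (-0.22), the epithelial mesenchymal transition list (0.078), the collagens and matrix list (2.08), the cytosolic ribosomal proteins list (0.20) and the fibroblast list (-0.14) in E20/p53 against p53 and Cyp2f2 (-1.33) and Pik3ca (0.064) in E20 against p53 reversed. Of these, Des and Wfdc2 in p53 against WT, Pitpnm3, Itgb4, Chrna1 and the collagens and matrix list in E20/p53 against p53 and Cyp2f2 in E20 against p53 passed in the other direction. In all, 27 named gene results and 15 lists lost their call, Pik3ca (-0.036) in E20/p53 against p53 among them, and Trp53 (0.17) in E20/p53 against E20 passed. The score differs between groups, so it takes up part of their difference by construction.

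Averages over the 6 sets leave 2 residual degrees of freedom. With them limma called (in brackets the number at an unadjusted p under 0.05) 1 higher (1062) and 0 lower (565) in p53 against WT, 8 higher (1233) and 0 lower (840) in E20 against WT, 1 higher (987) and 0 lower (587) in E20/p53 against WT, 0 higher (340) and 0 lower (633) in E20/p53 against E20, 0 higher (99) and 0 lower (323) in E20/p53 against p53 and 0 higher (281) and 0 lower (348) in E20 against p53. Of 221 named gene calls 216 were lost, among them Pik3ca (-0.35) and Trp53 (1.66) in p53 against WT, Pik3ca (-0.53) and Trp53 (2.90) in E20 against WT, Pik3ca (-0.60) and Trp53 (3.19) in E20/p53 against WT, Pik3ca (-0.24) and Trp53 (1.53) in E20/p53 against p53 and Trp53 (1.24) in E20 against p53, with log2 changes as reported. Camera with an estimated correlation called 3 in p53 against WT, 3 in E20 against WT, 3 in E20/p53 against WT, 0 in E20/p53 against E20, 0 in E20/p53 against p53 and 1 in E20 against p53 lists (3 at an unadjusted p under 0.05 in each comparison with 0), and fry called 22 in p53 against WT, 28 in E20 against WT, 21 in E20/p53 against WT, 18 in E20/p53 against E20 and 15 in E20 against p53.

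Whole sets were left out in turn. Lists lost their call 2 times without E20 1 to 3, 7 times without E20 4 to 6, 15 times without E20/p53 1 to 3 and 7 times without E20/p53 4 to 6. Named genes lost it 0, 1, 3 and 2 times. Fdps lost it in E20/p53 against E20 without E20 4 to 6 (-0.34) or E20/p53 4 to 6 (-0.65). Cdkn1a lost it in E20/p53 against WT without E20/p53 4 to 6 (0.44). Casp1, Mdm2 (-0.64) and Pik3ca lost it in E20/p53 against p53 without E20/p53 1 to 3. For lists, reversed means camera's direction against the other genes. By median the collagen list in E20/p53 against E20 here, and the fibroblast list in E20/p53 against p53 with the covariate, kept their sign. The ribosomal list changed its sign without E20/p53 1 to 3 against E20 (0.032) and p53 (0.031), and its call was lost. Without E20 1 to 3, Pik3ca (-0.22) in E20/p53 against E20 passed, Cdkn1a (-0.40) in E20 against p53 reversed, and camera called 14 lists in E20 against p53. Without E20 4 to 6, Pik3ca (0.078) in E20/p53 against E20 reversed and Pik3ca (-0.32) in E20 against p53 passed. Without E20/p53 1 to 3, Pik3ca (0.017) and the collagens and matrix list (-0.048) in E20/p53 against E20 and the collagens and matrix list (0.59) in E20/p53 against p53 reversed, of which the last passed in the other direction, Trp53 (0.69) in E20/p53 against E20 passed and Pik3ca (-0.16) in E20/p53 against p53 lost its call. Without E20/p53 4 to 6, Trp53 (-0.11) and the cholesterol synthesis list (0.026) in E20/p53 against E20 reversed, and counts were 4778 lower in E20/p53 against E20 and 4766 higher and 4968 lower in E20/p53 against p53. The cause was not tested.

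With each replicate left out in turn, no named gene or list reversed. Counts for E20/p53 against p53 ranged from 1111 to 2358 higher and from 1214 to 2333 lower, and camera called 6 to 11 lists there. Trp53 in E20/p53 against E20 ranged from 0.21 to 0.39, and Pik3ca in E20/p53 against p53 from -0.26 to -0.22. The other counts of genes stayed within 1.5 times those reported. Over all single left-out replicates, named genes lost their call 26 times and gained it 4 times, and lists lost it 34 times. Depth limits genes near 0, and the tests cover the 15235 of 26143 genes that passed the filter.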

Other observations

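The genes in this part were chosen after their values were seen, and no tests were made on them. Rn45s took 3.33% of the reads of 1 p53 library, and 0.0824% to 0.479% in the sets other than p53. Cdkn2a, which encodes the inhibitors p16 and p19ARF, was at 288 ± 22.3 CPM in WT, 236 ± 5.81 in p53, 26.7 ± 0.21 in E20 1 to 3, 16.9 ± 0.256 in E20 4 to 6, 142 ± 4.72 in E20/p53 1 to 3 and 376 ± 6.41 in E20/p53 4 to 6 (n = 3 libraries each).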
